A study of Homo sapiens with 2 samples.

How the data were processed

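Messenger RNA was sequenced from 1 untreated parental culture and 1 sorafenib-selected culture, both labelled HepG2. The groups were taken from the treatment and genotype labels, and the selection doses of 2.5, 0.5 and 7 µM from the protocol text of the labels. The authors deposited 3 tables with the same 50868 genes, and their values were used from where the authors stopped.

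The authors' tables hold whole-number counts per gene and library, per the file headers, not normalized. Per the submitters' processing notes, reads were handled with bcl2fastq 2.19, HISAT2 2.0.4 and StringTie 1.3.0 on build GRCh38. The annotation release, the counting settings and whether strand was used are not given in the sources used here, so reads of genes that overlap on opposite strands may not be separable. The deposited FPKM equals, by a check on the file, the count divided by a gene constant and by the library's total count. Per the file headers, a further deposited table gives the authors' own comparison with a log2 fold change, a p-value and a q-value, whose test is not given in the sources used here. The log2 fold change of the authors equals the log2 ratio of the deposited FPKM without a pseudocount. That table compares 1 library with 1 library, and its p-values and q-values were not used as evidence of a difference between the conditions.

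Counts were scaled to CPM, counts relative to library depth, with trimmed mean of M values (TMM) factors from edgeR 4.0.16 in R 4.3.3, with no model fitted. The factors were 1.00 for the parental and 0.997 for the resistant library. The log2 ratio was log2 of resistant CPM plus 1 over parental CPM plus 1, which understates the difference of genes with low values. Folds are ratios of CPM without a pseudocount, with an exact Clopper-Pearson 95% interval of the ratio of the 2 counts given their sum. A gene was measured when its larger CPM was at least 1, and past the size rule when its log2 ratio was at least 1 or at most -1. A fold against a count of 0 was computed against a floor of 3 counts per library and is written as a lower bound. This bound is 1-sided, and the limit of the 2-sided interval for the same gene is lower. PCR copies are not independent molecules, and neither intervals nor floors cover variation between cultures. With 1 library per group no test of the conditions was made, and no p-value across genes is given.

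The rule for named genes took the 12 highest and 12 lowest log2 ratios among protein-coding genes past the size rule whose larger CPM was at least 10. It added for each described list up to 4 members with the largest absolute log2 ratio, or up to 2 where no member was past the size rule, and a few reference genes of the line and the drug whatever their values (among them ALB, AFP, ABCB1, ABCC1, ABCG2, BRAF, EGFR, CDH1, VIM and MKI67). Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen; these are the further hepatocyte genes with few or no counts, VTN, APOM, LCAT, CPS1, KRT7, TXNDC5, BCL2L2-PABPN1, COL1A1, COL1A2, COL3A1, POSTN, PDGFRA, RN7SL2 and CDH5. The grouping, the measure, the size rule, the lists, the named-gene rule and most alternatives were fixed before the data were examined.

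The 59 lists covered hepatocyte functions, drug transport and metabolism, growth signalling, stress, metabolism, proliferation, cell death, immunity and markers of other cell types. They were matched by symbol, and 19 of 1314 symbols had no entry. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A median under percentile 2.5 or over 97.5 is said to stand apart. The same was done for GO and KEGG terms of the deposited annotation with 10 to 300 measured genes, and for chromosomes.

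Gene types and exons came from GENCODE 29, also on GRCh38, in which 50111 of the 50868 identifiers were found and 47538 had identical coordinates. Genes were said to share exons when exons of both overlap on the same strand. Chromosomes, starts and ends are those of the deposited tables.

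The calculation was tested on simulated data, with 14524 genes drawn as Poisson counts at the levels and depth of these libraries. Of genes set to a 2.5-fold difference between resistant and parental, 87.3% were past the size rule, and 100% of those at 10 CPM or more. For a 4-fold difference these shares were 97.1% and 100%, for a 1.5-fold difference 0%, and for unchanged genes 0.0072%. Intervals held the true ratio for 95.1% of genes. Of 20 simulated lists shifted by a constant, 100% stood apart, and of 200 lists that were not shifted, 1.5% stood apart as higher. The constant was larger than the median of most real lists that stood apart, and smaller shifts were not tried. The simulated genes varied independently and by counting error only. These shares therefore do not cover variation between cultures or genes that are regulated together.

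Alternatives were total count, median-of-ratios (DESeq2 1.42.0) and upper-quartile scaling, the deposited FPKM, pseudocounts of 0.1 and 5, no filter or a larger value of at least 10, an absolute log2 ratio of at least 2, protein-coding genes only, the mean in place of the median, 40 bins, and chromosomes without the genes past the size rule. Sums over exon-sharing genes, and leaving these genes out, were added after the data had been seen. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.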

Results

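RNA sequencing was carried out on 2 cultures of cells labelled HepG2, a human liver cancer line that is widely used as a model of the hepatocyte and of hepatocellular carcinoma. The parental culture was untreated. The resistant culture had been selected with sorafenib, an oral inhibitor of several kinases that is given for liver cancer. According to the labels, selection started at 2.5 µM and went up in steps of 0.5 µM to 7 µM. Each group had 1 library. The counts of the parental library summed to 18067146 over 21623 genes with a count, and those of the resistant library to 16811907 over 21742 genes. Mitochondrial genes took 7.37% of the parental counts (95% Wilson interval 7.35 to 7.38) and 6.91% of the resistant counts (6.90 to 6.92). With 1 library per group no value has an SD or a replicate check, and each interval covers counting error only. A count of 0 allowed a level of up to 0.166 CPM (counts relative to library depth, scaled with TMM factors) in the parental library and 0.179 CPM in the resistant library, the worth of 3 counts.

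Genes that mark the hepatocyte had few or no counts in either library. ALB, which encodes albumin, and AFP, which encodes alpha-fetoprotein, had 0 counts in both, as had TTR, SERPINA1, FGA, FGB, APOA1, APOB and GPC3. Of 44 genes in the fixed lists of hepatocyte plasma proteins and of apolipoproteins and lipoprotein assembly, 30 had 0 counts in both libraries and 34 had at most 3 counts in both. The 44 genes together had 198 counts in the parental and 191 in the resistant library. The plasma protein list had 1 measured member of 28, VTN, with 59 and 51 counts. The apolipoprotein list had 2 measured members of 16, APOM with 48 and 29 counts and LCAT with 49 and 71. HNF4A and FOXA2, transcription factors of the hepatocyte, had at most 2 counts each in either library. HepG2 is known to secrete albumin and apolipoproteins, so the names parental and resistant stand throughout for the libraries so labelled.

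CPS1 and some epithelial and mesenchymal genes were abundant in both libraries. CPS1, the mitochondrial carbamoyl phosphate synthetase of the urea cycle, stood at 3062 CPM in the parental and 2500 CPM in the resistant library. EGFR, the epidermal growth factor receptor, stood at 3137 and 3993 CPM, and KRT7, a keratin of simple and ductal epithelia, at 1892 and 2516 CPM. VIM, the mesenchymal intermediate filament, stood at 550 and 499 CPM, whereas CDH1, the epithelial cadherin, had 5 and 20 counts. The collagen genes COL1A1 and COL3A1 stood at 142 and 217 CPM in the parental library. In the resistant library they stood at 156 and 195 CPM.

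**Figure D1:**
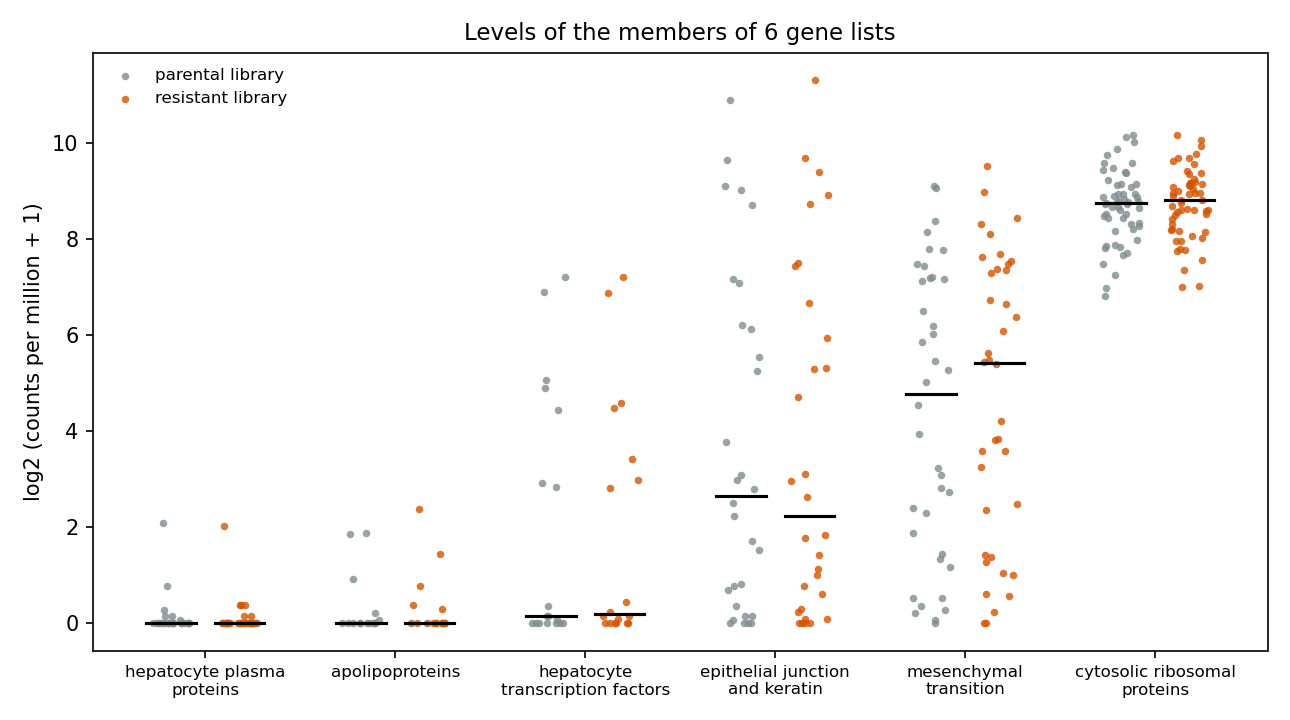
Levels of all members of 6 fixed gene lists in the parental (grey) and resistant (orange) library, as log2 of CPM plus 1; each point is 1 gene, horizontal jitter has no meaning and black bars are medians over genes. Plasma protein and apolipoprotein genes lie at or near 0 in both libraries, with 30 of the 44 genes at 0 counts in both, while cytosolic ribosomal protein genes are high in both.

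The comparison asked which genes differ in expression between cells selected to grow in sorafenib and the parental cells. The gene with the most counts behind a large difference was SCRN1, which encodes the cytosolic protein secernin-1, at 15.96-fold the parental level in the resistant library (95% interval 15.5 to 16.4). Target genes of the Hippo pathway cofactors YAP and TAZ were higher as a list in the resistant library. Among them CCN1 was at 3.46-fold (3.31 to 3.62) and ANKRD1 at 3.61-fold (3.06 to 4.27). Output genes of the ERK cascade, and genes of integrins, laminins and basement membrane, were also higher as lists. Genes of gluconeogenesis, NRF2 targets and genes of DNA replication were lower as lists. The list of drug efflux transporters did not stand apart, and ABCB1, the P-glycoprotein gene, was at 0.786-fold (0.690 to 0.895).

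Of 14686 measured genes, 192 were higher and 146 lower in the resistant library by the size rule, a log2 ratio of at least 1 or at most -1. These 338 genes were 2.30% of measured genes. The log2 ratio of the middle 50% of measured genes lay between -0.15 and 0.16, that of the middle 95% between -0.71 and 0.78, and the median was -0.0018. Across measured genes, which are not independent replicates, Pearson's r of log2(CPM + 1) between the libraries was 0.984. Among the 10403 genes that reached 10 CPM in either library, 117 were higher and 90 lower. Of the genes past the size rule, 96 (28.4%) share exons with another gene on the same strand, against 2056 of all 14686 measured genes. Without them, 144 genes were higher and 98 lower. The authors' deposited table compared 21518 genes and called 271 UP and 221 DOWN. All 338 genes past the size rule were called there in the same direction. That table rests on the same 2 libraries and its fold change has no pseudocount, so this agreement follows largely from how both measures are built. The smallest absolute log2 fold change of a called gene in the authors' deposited table was 1.004, and 145 of the 492 called genes (29.5%) share exons.

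**Figure D2:**
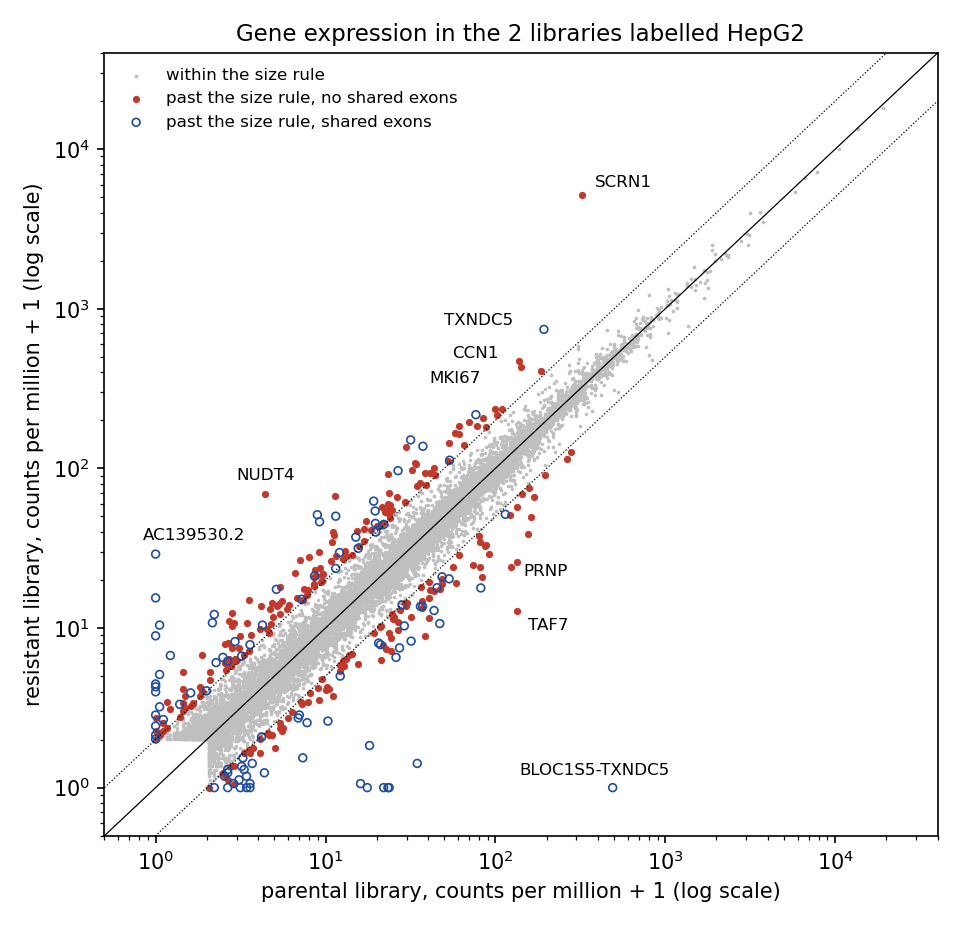
Expression of 14686 measured genes in the parental (x axis) and resistant library (y axis), both as CPM plus 1 on log scales; each point is 1 gene, the solid line marks equality and dotted lines the size rule. SCRN1 lies far above the line at 323 and 5154 CPM, and many of the genes at 0 CPM in 1 library share exons with a neighbour (open blue circles), such as BLOC1S5-TXNDC5 at 489 and 0 CPM.

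SCRN1 (ENSG00000136193; chromosome 7, 29920103 to 29990289 on the minus strand, GRCh38) had 5852 counts in the parental and 86389 in the resistant library. It took 0.514% of all resistant counts (0.510 to 0.517), and its rank by count went from 425 to 7. NUDT4 (ENSG00000173598; chromosome 12, 93377883 to 93408146), a diphosphoinositol polyphosphate phosphatase gene with near-identical copies elsewhere in the genome, was at 19.8-fold (15.3 to 26.0) with 62 and 1134 counts, a value that is uncertain for that reason. TMEM250 was at 6.37-fold (5.46 to 7.47), FAM217B at 6.29-fold (4.33 to 9.40), MAPK1IP1L at 4.70-fold (4.27 to 5.18) and DOK7, which encodes an adaptor of a muscle receptor kinase, at 5.86-fold (3.98 to 8.89). These 6 genes share no exons with another gene. DGKH, a diacylglycerol kinase gene, was at 6.32-fold (5.29 to 7.60), and NFAT5, the transcription factor of osmotic stress, at 4.88-fold (4.45 to 5.36). Both overlap minor transcripts and stayed past the size rule in the sum over the locus, at log2 ratios of 2.51 and 2.34. BCL2L2, the gene of the survival protein BCL-w, was at 5.51-fold (4.61 to 6.61), and at 3.02-fold when summed with its read-through partner BCL2L2-PABPN1.

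TAF7 (ENSG00000178913; chromosome 5, 141260225 to 141320821), a subunit gene of the general transcription factor TFIID, had 2416 counts in the parental and 197 in the resistant library and was 11.3-fold lower (9.81 to 13.2). PRNP, the prion protein gene, was 5.33-fold lower (4.78 to 5.95), and CHP1, which encodes a partner of sodium-proton exchangers, was 5.32-fold lower (4.79 to 5.91). RNF4, a ubiquitin ligase gene for SUMO-modified proteins, was 4.82-fold lower (4.24 to 5.49) and RTL10 4.76-fold lower (4.02 to 5.67). Summed with the genes they overlap, RNF4 and RTL10 had log2 ratios of -1.10 and -1.68.

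The remaining genes of the largest differences were read-through or overlapping loci whose sums were within the size rule. BLOC1S5-TXNDC5 (chromosome 6, 7881522 to 8064364) had 8858 counts in the parental and 0 in the resistant library, at least 2732-fold lower against the floor of 3 counts. TXNDC5, an endoplasmic reticulum disulfide isomerase gene that lies within it, went the other way from 3478 to 12432 counts, and the locus summed to a log2 ratio of 0.11. ATP5MF-PTCD1 had 411 and 0 counts, ATP6V1G2-DDX39B 404 and 0, and AC011462.1 301 and 0, with log2 ratios of the sums of -0.03, 0.03 and 0.08. AC007192.1 was 80.6-fold lower (38.9 to 201) and AC023055.1 20.6-fold lower (12.1 to 38.0), with sums at -0.39 and -0.05. In the other direction AC139530.2 had 0 and 470 counts, at least 169-fold higher, with a sum at -0.09. AC011511.4 was at 9.19-fold (5.89 to 15.02) and FMC1-LUC7L2 at 4.69-fold (3.999 to 5.52), with sums at 0.01 and -0.01. In all, 14 of the 24 genes with the largest ratios share exons, and the locus sum was within the size rule for 9 of them. The 221 protein-coding genes past the size rule that share no exons had a median longest annotated 3′ UTR of 1903 bases, above the 1052 to 1527 bases that held the middle 95% of expression-matched random sets.

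Of 59 gene lists fixed in advance, 51 had at least 5 measured members. The median log2 ratio of 12 lists lay above the middle 95% of 10000 random lists matched on expression, and that of 7 lists lay below it, where 1.27 would be expected by chance in each direction. These percentiles describe the 2 libraries and are not tests of the conditions. Random lists hold independently drawn genes, whereas members of a fixed list can be regulated together. Some fixed lists also share members, so the lists that stood apart are not independent findings.

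Targets of YAP and TAZ, cofactors that carry signals of cell shape, adhesion and density, had the highest median of any described list. All 23 members were measured, 21 had a positive log2 ratio and 4 were past the size rule, and the median of 0.41 exceeded every random list. Besides CCN1 and ANKRD1, CCN2, a matricellular growth factor gene, was at 2.75-fold (2.43 to 3.11), and F3, which encodes tissue factor, at 2.44-fold (2.17 to 2.76). The ERK output list had a median of 0.39, also above every random list, with 17 of 23 measured members positive and 2 past the size rule. DUSP4, a phosphatase gene that ERK induces, was at 3.40-fold (2.87 to 4.05), and IL11, a cytokine gene, at 3.10-fold (2.12 to 4.61). FOSL1, which encodes an AP-1 subunit, was at 2.18-fold (1.57 to 3.07), with a log2 ratio of 0.92. In the list of integrins, laminins and basement membrane 18 of 25 measured members were positive, and the median was 0.34, above every random list. ITGA2, the collagen-binding integrin subunit gene, was past the size rule at 2.13-fold (1.83 to 2.47).

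Mesenchymal transition genes had a median of 0.20 (percentile 99.99) with 3 of 33 measured members past the size rule. These were COL6A2 at 3.06-fold (2.36 to 4.02), COL6A1 at 2.32-fold (1.89 to 2.87) and THBS1, the thrombospondin-1 gene, at 2.32-fold (2.13 to 2.53). ZEB1, a transcription factor that represses epithelial genes, was at 1.95-fold (1.72 to 2.21), and VIM was at 0.908-fold (0.882 to 0.935). Markers of fibroblasts, kept as a list of another cell type, were also higher, with a median of 0.26 over 7 measured members. That median lay at percentile 99.1, and between percentiles 97.2 and 99.6 over the 11 alternative settings, 3 of which put it within the middle 95%. LUM was at 2.51-fold (1.96 to 3.24) and past the size rule, whereas COL1A2 and PDGFRA had 0 CPM in both libraries. Epithelial junction and keratin genes did not stand apart, with a median of 0.03 and none of 20 measured members past the size rule. TJP3, a tight junction gene, had a log2 ratio of -0.95 and CLDN1 one of 0.94. CDH1 was at 4.32-fold (1.57 to 14.7).

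Growth factor ligands had a median of 0.20 (percentile 99.9), and 2 of 23 measured members were past the size rule. NRG1, the neuregulin-1 gene, was at 2.76-fold (2.39 to 3.20), and FGF2 at 2.12-fold (2.01 to 2.25). Receptor tyrosine kinases had a median of 0.17 (percentile 99.9) with none of 20 measured members past the size rule. Their percentile ranged down to 96.4 over the alternatives, and 4 of 11 alternatives put the list within the middle 95%. EGFR was at 1.27-fold (1.26 to 1.29), and EPHB2 had the largest ratio of the list, 1.91-fold (1.45 to 2.54). The kinases that sorafenib inhibits had a median of 0.15 (percentile 97.1). DDR2, a collagen receptor kinase gene, was their 1 member past the size rule at 4.08-fold (3.03 to 5.56). BRAF was at 1.12-fold (1.02 to 1.22). Cytokines and chemokines had a median of 0.32 (percentile 99.99), with IL11 as the 1 member of 17 past the size rule. With the deposited FPKM this list lay at percentile 96.8.

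Long non-coding RNAs of liver cancer had a median of 0.27, above every random list, with 1 of 17 measured members past the size rule, LUCAT1 at 3.04-fold (2.17 to 4.32). HOTAIR had a log2 ratio of -0.78, against the direction of the list. Replication-dependent histone genes had a median of 0.28 (percentile 99.8) with none of 16 measured members past the size rule. Histone genes are near-identical copies of each other, so the values of single members such as H3C4, with 12 and 31 counts, are uncertain. Genes of cholesterol synthesis and uptake had a median of 0.17, above every random list, with 21 of 25 members positive. The exception in size was SC5D, the sterol desaturase gene, which was 2.39-fold lower (2.13 to 2.69) and past the size rule. Using the mean in place of the median put this list at percentile 97.2. Integrated stress response genes had a median of 0.08 (percentile 99.2), and none of 36 measured members was past the size rule. DDIT3, the gene of the stress factor CHOP, had a log2 ratio of -0.86 and FGF21 one of 0.65. The mean of this list lay at percentile 95.7.

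Genes of gluconeogenesis and glycogen had the lowest median, -0.27 (percentile 0.090), with 1 of 8 measured members past the size rule. PCK1, the cytosolic carboxykinase of gluconeogenesis, had 73 and 13 counts and was 5.19-fold lower (2.86 to 10.2). SLC37A4, the glucose-6-phosphate transporter gene, had a log2 ratio of -0.62. With the deposited FPKM this list lay at percentile 3.37. Wnt targets had a median of -0.25 (percentile 0.520), with MYC at a log2 ratio of -0.56 and RNF43, a ubiquitin ligase gene that restrains Wnt receptors, at -0.55. Of their 10 measured members 7 were negative and 3 positive, with none past the size rule, and the mean lay at percentile 5.83. MYC is also a member of the ERK output list, where it went against the direction of the list. NRF2 targets, the oxidative stress and detoxification genes, had a median of -0.14 (percentile 0.080) with 17 of 27 measured members negative. AKR1C1 was 3.16-fold lower (2.78 to 3.60) and AKR1C2 2.72-fold lower (2.24 to 3.31), both aldo-keto reductases of a near-identical family whose counts are uncertain, while TXNRD1, the thioredoxin reductase gene, was at 1.63-fold (1.59 to 1.68).

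Replication and S phase genes had a median of -0.17, below every random list, and 25 of 31 members were negative with none past the size rule. MCM5, a helicase subunit gene, had the largest ratio at 0.679-fold (0.641 to 0.719), and E2F1 was at 0.756-fold (0.682 to 0.837). Mitosis genes had a median of -0.0038 (percentile 51.9) and a mean of 0.10, of the opposite sign. MKI67, the proliferation antigen gene (ENSG00000148773; chromosome 10, 128096659 to 128126385), was at 3.07-fold (2.94 to 3.21) and FOXM1, a transcription factor of mitotic genes, at 2.16-fold (2.04 to 2.28). The other 30 mitosis genes had log2 ratios between -0.17 and 0.23. Glycolysis genes had a median of -0.08 (percentile 1.75). PKM, the pyruvate kinase gene, had a log2 ratio of -0.79. Fatty acid synthesis and storage had a median of -0.12 (percentile 0.950) and none of 21 measured members past the size rule, with DGAT2 at -0.64 and PLIN4 at -0.63. Its percentile ranged up to 6.87 over the alternatives. Mitochondrially encoded mRNAs had a median of -0.11 (percentile 0.935), with 12 of 13 negative and MT-ND6 lowest at 0.767-fold (0.736 to 0.7995). That list lay at percentile 3.52 with exon-sharing genes left out.

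The other 32 described lists did not stand apart, with medians between -0.11 and 0.15. Under at least 1 alternative 7 of them did, as lower the lists of hepatocyte transcription factors, the urea cycle and interferon-stimulated genes, and as higher those of epithelial junctions, oncofetal genes, sorafenib kinase targets and apoptosis. Drug efflux transporters had 10 measured members, none past the size rule, and a median of -0.11 (percentile 5.86). The broader KEGG term of ABC transporters, with 24 measured genes and 1 past the size rule, had a median of -0.11 and stood apart as lower (percentile 1.46). ABCC2 was at 0.759-fold (0.716 to 0.804), ABCG2 at 1.54-fold (1.13 to 2.13) and ABCC1 at 1.03-fold (0.972 to 1.10). Drug uptake transporters had a median of 0.06 and cytochrome P450 drug oxidation genes one of 0.12, and neither they nor drug conjugation enzymes, at 0.02, had a member past the size rule. Hepatocyte transcription factors had a median of -0.11 over 7 measured members. FOXA1, a pioneer factor of liver development, was 3.02-fold lower (2.45 to 3.76), the 1 member past the size rule. Coagulation and complement had a median of 0.02. The urea cycle and amino acid breakdown list had a median of -0.03 and that of bile acid synthesis and transport 0.08, with CPS1 at 0.816-fold (0.806 to 0.827) and FGFR4 at 1.65-fold (1.40 to 1.94).

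Apoptosis regulators had a median of 0.07 (percentile 92.0) with 3 members higher and 1 lower past the size rule. These were BCL2L2, BCL2L11, the gene of the death-promoting protein BIM, at 3.58-fold (2.97 to 4.34), FAS, a death receptor gene, at 2.20-fold (1.75 to 2.77), and TNFSF10, the gene of the ligand TRAIL, which was 3.01-fold lower (1.798 to 5.24). Targets of p53 had a median of -0.06, with FAS as the 1 member past the size rule. Cyclin-dependent kinase control had a median of -0.09 (percentile 3.24), with E2F3 at a log2 ratio of -0.98 and CDKN2A at 0.88. Oncofetal and liver cancer genes had a median of 0.10, and PEG10, a retrotransposon-derived imprinted gene, was at 4.05-fold (3.63 to 4.53). TERT, the telomerase gene, had 1 and 17 counts. Autophagy and lysosome genes had a median of -0.03, and GABARAPL1, an autophagosome gene, was 2.17-fold lower (2.04 to 2.30). Fatty acid oxidation and PPAR targets had a median of -0.04, and ACSL5, an acyl-CoA synthetase gene, was at 2.22-fold (1.79 to 2.78). The TGF-beta and SMAD list had a median of 0.05, with CCN2 as its 1 member past the size rule.

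Interferon-stimulated genes had a median of -0.09 (percentile 4.74) and antigen presentation genes one of -0.03, with OASL at a log2 ratio of -0.68 and HLA-C at -0.72. Ferroptosis regulators had a median of -0.05, with NFE2L2, the NRF2 gene, at -0.92. Iron handling genes had a median of 0.05 and endoplasmic reticulum chaperones one of 0.07, with BMP6 at 0.57 and DNAJB11 at 0.30. Heat shock genes had a median of -0.06, hypoxia response genes one of -0.0082 and the pentose phosphate and one-carbon list one of -0.02, with HSPA8 at -0.40 and EPAS1 at 0.81. Nuclear respiratory chain subunits had a median of 0.0086 and cytosolic ribosomal proteins one of 0.04, with ATP5F1A at -0.68 and RPS19 at -0.65. Stem and progenitor markers had a median of 0.04 and the Notch and Hedgehog list one of 0.05, with KLF4 at -0.54 and HEY1 at -0.79. The biliary list of another cell type had a median of -0.10, with MUC1 at 0.90, and the squamous and other epithelia list one of 0.10, with KRT17 past the size rule at 2.46-fold (2.25 to 2.70). In 8 lists, none of which stood apart, the mean had the opposite sign of the median. They were the lists of drug uptake, cytochrome P450, drug conjugation, stem markers, hypoxia, nuclear respiratory chain, mitosis, and Notch and Hedgehog.

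The 8 lists with fewer than 5 measured members included, besides plasma proteins and apolipoproteins, metallothioneins and acute phase genes with 4 each, and small nuclear and cytoplasmic RNAs with 2. Of the lists of other cell types, endothelial and neural markers had 4 measured members of 11 each and leukocyte markers 2 of 13. RN7SL2 and CDH5, the endothelial cadherin gene, were their members past the size rule, with 28 and 85 counts and with 20 and 72 counts.

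**Figure D3:**
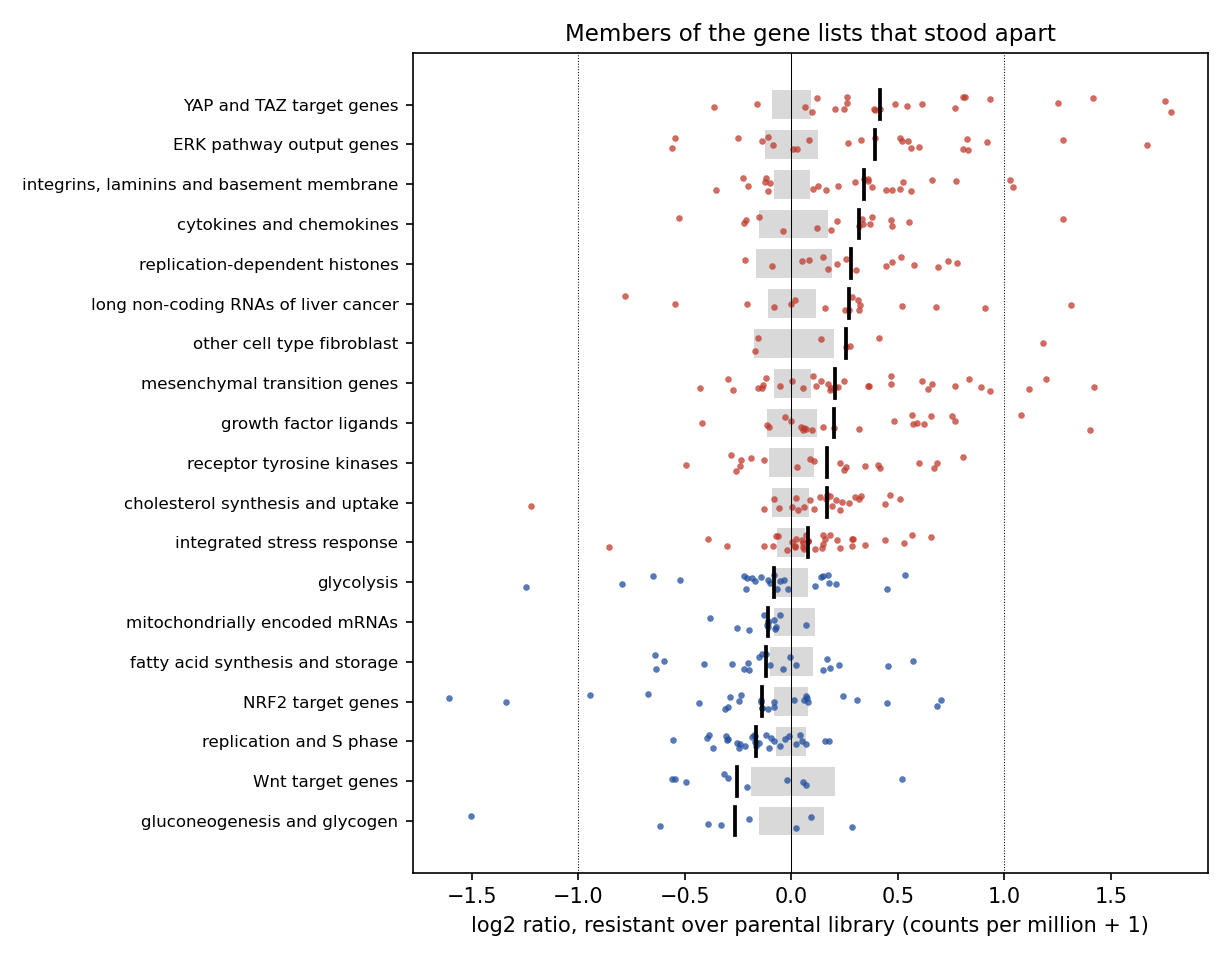
Log2 ratio of resistant over parental CPM plus 1 (x axis) for the measured members of the 19 lists that stood apart (y axis); each point is 1 gene, black bars are list medians, grey bands hold the middle 95% of 10000 random medians matched on expression and dotted lines mark the size rule. Medians run from 0.41 for YAP and TAZ targets down to -0.27 for gluconeogenesis and glycogen, and most members lie within the size rule.

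Of the annotation terms deposited by the authors, 298 KEGG pathways and 4800 GO terms had 10 to 300 measured genes. Among KEGG pathways 23 stood apart as higher and 13 as lower, against 7.45 expected by chance each way. ECM-receptor interaction had a median log2 ratio of 0.18, with 6 of 50 genes past the size rule, and focal adhesion one of 0.11, both above every random set. Ribosome biogenesis (0.07) and Hippo signaling (0.06) were also among the 23. Lysosome (-0.08), glycerolipid metabolism (-0.16), the pentose phosphate pathway (-0.13) and DNA replication (-0.10) were among the lower ones. Among GO terms 338 stood apart as higher and 205 as lower, against 120 expected each way. Hemidesmosome assembly (0.41), extracellular matrix structural constituent (0.32) and preribosome (0.13) were among the higher terms, and NAD metabolic process (-0.11) and cellular carbohydrate catabolic process (-0.11) among the lower. Terms share genes, so these counts are not of independent sets.

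Median log2 ratios per chromosome were small. Chromosome 13 had the highest, 0.05 over 252 measured genes (percentile 99.9), chromosome 19 had -0.04 over 946 genes (percentile 0.010), and the 15 measured mitochondrial genes had -0.11 (percentile 0.785). The other chromosomes did not stand apart.

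Of the 171 genes taken by the rule for named genes, 56 were past the size rule, and 35 of these were past it under each other scaling, unit and pseudocount tried. The other 21 were within it on the deposited FPKM, with 1 added to each value, or with 5 added to each CPM. Among them were ACSL5, AKR1C2, BCL2L11, COL6A1, COL6A2, DDR2, DOK7, FAS, FGF2, IL11, ITGA2, LUCAT1, LUM, NRG1, PCK1, SC5D and TNFSF10. None of the 56 changed direction under these settings. Sums over exon-sharing genes are not among them.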

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

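The settings that sum counts over exon-sharing genes or leave these genes out were chosen after the data had been seen; all others were planned. The counts of 192 higher and 146 lower genes stayed within 1.5 times under 3 other scalings (186 to 189 higher, 150 to 154 lower), among protein-coding genes, without exon-sharing genes (144 and 98) and for sums over exon-sharing genes (153 and 111). Removing the filter on low values moves nothing, since a gene under 1 CPM cannot pass the size rule. The counts were 90 and 78 on the deposited FPKM, 431 and 315 with a pseudocount of 0.1, 83 and 68 with a pseudocount of 5, 117 and 90 with a larger value of at least 10, and 21 and 16 at an absolute log2 ratio of at least 2; a larger pseudocount, a higher minimum and a higher threshold exclude genes by construction. The lists that stood apart numbered 10 to 12 higher and 5 to 10 lower over all settings. Chromosomes that stood apart as higher numbered 1, and 2 on the deposited FPKM and with a pseudocount of 5; the cause was not tested. No list median that stood apart changed sign, and no named gene past the size rule did under the other scalings, unit and pseudocounts. Sums over exon-sharing genes were not part of this comparison for named genes. Depth limits genes near the floor of 3 counts, whose intervals span several-fold. No paired analysis was possible because the groups share only 1 replicate number.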

Other observations

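Of the tests below, those on the missing hepatocyte genes other than the one on neighbouring genes, the one on loci that share exons, and those on fibroblasts, on replicate cultures and on cycling cells were chosen after the result was seen, and the genes of this paragraph after their values were seen. Outside the protein-coding class, 4 genes that share no exons and reach 10 CPM were past the size rule, all 4 of them higher in the resistant library. LINC00707 was at 5.55-fold (4.03 to 7.78), LINC00052 at 3.44-fold (2.62 to 4.57), AL590004.3 at 2.58-fold (2.18 to 3.08) and UBA6-AS1 at 2.48-fold (1.96 to 3.15). UBA6-AS1 lies antisense to a coding gene, and its reads are uncertain without a statement on strand. IGFBP3, a YAP and TAZ target that binds insulin-like growth factors, had 5551 and 9816 counts and a log2 ratio of 0.93, just within the size rule. Counts of EEF1A1P5, a processed pseudogene, exceeded those of its parent gene EEF1A1 in both libraries. They were 120635 against 38268 in the parental and 110991 against 34370 in the resistant library. How reads of these near-identical copies were divided was not tested.

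SCRN1 was far higher in the resistant library. Gain of the chromosome segment around SCRN1 would raise its neighbours as well, but the 15 other measured genes within 1 Mb had a median log2 ratio of -0.023, and the highest was 0.42 against 3.99 for SCRN1. A change at the gene itself stays open as a hypothesis and was not tested. MKI67 and FOXM1 were higher, and a larger share of cycling cells would raise the other mitosis genes too; the median log2 ratio of the 30 others was -0.014, and the highest was 0.23. Why these 2 genes stood apart from the mitosis list was not tested.

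The 44 plasma protein and apolipoprotein genes had almost no counts in either library. Loss of hepatocyte expression during sorafenib selection would leave them in the parental library, where 6 of 44 had more than 3 counts. Regions around these genes missing from the count table would take neighbours along, but 67.8% (63.7 to 71.6) of the other protein-coding genes within 1 Mb had more than 3 counts, against 66.6% of all protein-coding genes. Cells of another line or without hepatocyte character under the HepG2 label remain a candidate explanation for both libraries, since 2 of 2 transcription factors asked (HNF4A and FOXA2) also had at most 3 counts. A different line and a HepG2 derivative that had lost this character before the selection were not told apart here. No further biological explanation was weighed.

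Genes past the size rule were enriched in loci that share exons. Of 74 such genes with a measured partner, 77.0% (66.3 to 85.1) had partners that differed the opposite way. Among 1144 genes within the size rule that share was 51.0% (48.2 to 53.9). Reads assigned to a different gene of the same locus in the 2 libraries would give such an excess. For 62 of the 74 the sum was within the size rule, but adding a more abundant partner can do this without any such assignment. For genes that share no exons, reads of long 3′ UTRs counted differently may contribute, since their median 3′ UTR lay at percentile 100 of matched random sets (99.97 for higher genes alone, 96.8 for lower genes alone). Regulation of genes with long 3′ UTRs by the resistant state predicts the same and stays open. Reads shared with listed pseudogenes could not be told apart from no such sharing, at percentile 89.5 of random sets.

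The lists of YAP and TAZ targets, ERK output genes and matrix genes each had a median above every random list. Reads assigned to a different gene of the same locus are argued against, since without exon-sharing genes the lowest percentile of the 3 list medians was still 100. Whether reads of long 3′ UTRs counted differently contribute to these 3 lists was not tested. Fibroblasts in the resistant culture would bring COL1A2 and other abundant transcripts. The 7 measured fibroblast markers had a median log2 ratio of 0.26, with 5 positive and 2 negative. Of 5 fibroblast markers under 1 CPM in the parental library 0 reached 1 CPM in the resistant library. A small share of fibroblasts need not lift such a marker to 1 CPM, so this count cannot exclude it. POSTN, 1 of the 5, was at 0.110 CPM in the parental and 0.716 CPM in the resistant library, and COL1A2 at 0 CPM in both; a test tried before it, the median log2 ratio of COL1A1, COL1A2 and COL3A1, gave 0 and decided nothing. Culture-to-culture variation unrelated to resistance, such as cell density at harvest, cannot be told apart from the selection with 1 parental library. An effect of sorafenib that may have been present at harvest cannot be told apart from a lasting effect of the selection either. A change in YAP and ERK activity with selection therefore stays a hypothesis, and no replicate bears on it.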
